A study of Homo sapiens with 77 samples.

How the data were processed

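The series holds 77 libraries of sorted memory Treg and memory Teff from blood of healthy controls and people with MS, made from lysed cells with a low-input full-length cDNA kit and sequenced in pairs, per the labels' protocols. The deposited table holds RSEM expected counts, 1 column per library, which need not be whole numbers, and a mean of 22.7% of the values per library was not whole. The submitters' processing notes name Trimmomatic, FastQC, STAR 2.5.2, Picard and RSEM with the GRCh38 (hg38) genome, without their roles or order, the annotation release, the strand setting or the rule by which genes had been filtered. Antisense and overlapping genes, pseudogenes and paralogs are therefore uncertain where their reads could have been divided. Of 15541 gene IDs 15500 matched GENCODE release 29, which gave chromosome, position, length and GC content. The labels do not say that equal numbers mean the same person, nor name a batch.

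Expected counts were rounded to whole numbers, and XIST, its antisense gene and Y-linked genes (16 in all) were left out of every test. Genes with low counts were removed with filterByExpr by group, which left 14324 genes, and 14121 without the libraries against their label. All libraries entered 1 fit with a mean per group (edgeR 4.0.16, TMM factors, quasi-likelihood F test, R 4.3.3), and p-values were adjusted by Benjamini-Hochberg over all tested genes, with a threshold of 0.05. Every adjusted p of a gene comes from this quasi-likelihood test, and every adjusted p of a list from camera (limma 3.58.1) over the lists of that comparison, with a preset correlation or, where stated, one estimated per list. A total of 38 gene lists, on T cell subsets, signalling responses, metabolism and markers of other blood cells, had been fixed before the data were examined, as had the comparisons, the tests and the alternatives not named as added. A list was tested where at least 3 of its genes were measured. Levels of genes are CPM with library sizes scaled by TMM factors, estimated anew for the 66 libraries, so values of the same library can differ slightly. Marker scores and the number of genes above 1 CPM used unscaled library sizes.

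The genes named are 9 focal genes (CD4, FOXP3, IL2RA, IL7R, CTLA4, IKZF2, TIGIT, PRDM1 and SGK1), up to 8 genes per direction and comparison with the smallest p among those past the threshold (mean CPM of at least 2, and for Treg against Teff an absolute log2 fold change of at least 1), and up to 4 members of each list with an adjusted p under 0.05 or 3 members past the threshold. Where none passed, the 2 with the smallest p each way are given as not passing. Immune receptor segments, HLA-DRB, HLA-DQ and KIR genes were not named, since their counts depend on a person's alleles.

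A library was against its label when its difference between mean Treg core and mean conventional T cell markers, in log2(CPM + 1), lay beyond the midpoint (0.5) between the group medians. Libraries of the same number deviated together in Treg and Teff once the libraries against their label were left out (correlations of at least 0.189 over 17 HC pairs and 0.12 over 12 MS pairs). With all libraries 1 of 19 HC pairs and 5 of 16 MS pairs lay at or below 0.1 (lowest -0.193 and -0.665, median 0.462 and 0.202). HC with MS numbers did not pair. The main fit used no pairing. As labelled, the fits with the donor as a random effect or the replicate block still joined all libraries by number, those against their label included. No 2 libraries of a group agreed within sampling noise (lowest chi-square per gene 19.7). P-values measure the spread between libraries, since nothing in the labels states separate donors.

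Alternatives were RLE factors, DESeq2 1.42.0, limma-voom with and without the donor as a random effect, no filter, a mean CPM of at least 5, only the groups compared, only donors with both cell types, the replicate number as a block, detected genes, surrogate variables (sva 3.50.0, at most 5) or a sex-linked score as covariates, a robust fit, a threshold of 0.01 and the loss of 2 libraries far from their group. Added after the data were seen were the loss of the 11 libraries against their label, offsets for length and GC content, the loss of 4 Treg libraries with over 8% of counts from MALAT1 and the loss of the HC Teff library with the most platelet reads. Other divisions of the libraries numbered 60 per comparison, the real one included. Correlations were tested with 100000 permutations (Python 3.11.15, scipy 1.17.1).

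The depth was 3.53 M to 44.7 M estimated reads per library. The edgeR step was tested on simulated data with the real means and library sizes, independent libraries and no pairing. For MS against HC in Treg over 14324 genes it found 50% of 100 genes changed by 1 on the log2 scale and 18% of 100 changed by 0.5, with 3 unchanged genes called. Over 14121 genes without the libraries against their label it found 43% and 13% in Treg (5 unchanged genes called) and 48% and 6% in Teff (1 called). For Treg against Teff in HC over 14324 genes it found 50% and 13% (3 called).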

Results

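RNA of memory CD4 T cells was measured in blood from healthy controls (HC) and people with multiple sclerosis (MS). Regulatory T cells (memory Treg, with high CD25 and low CD127 on the surface) and effector T cells (memory Teff, with low or no CD25 and high CD127) had been sorted, and each library holds 1 cell type of 1 number in the labels. There were 20 HC Treg, 20 HC Teff, 17 MS Treg and 20 MS Teff libraries, 77 in all, and 35 of the 42 numbers had both cell types. The deposited table gave 15541 genes, and the libraries held between 3.53 M and 44.7 M estimated reads. Between 11437 and 12844 genes per library lay above 1 CPM (the count scaled to 1e6 counts per library).

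The markers of the sorted cells went against the label in 11 of the 77 libraries. The markers were those of Treg (FOXP3, IL2RA, IKZF2, CTLA4 and other genes of the Treg core list) and of conventional T cells (IL7R, SATB1, THEMIS and others), scored as a difference of mean log2(CPM + 1). The 34 Teff libraries on their label's side scored between -4.20 and -2.75, and the 32 Treg libraries on their label's side between 0.61 and 1.94. The other 5 libraries labelled Treg scored between -4.08 and -3.11, and the other 6 labelled Teff had a median of 1.11, with the lowest at -0.57. They were 2 of 20 HC Treg, 0 of 20 HC Teff, 3 of 17 MS Treg and 6 of 20 MS Teff libraries. Genes in none of the lists put 10 libraries against their label, all 10 among the 11. Each comparison below is therefore given as labelled and again with the 66 other libraries, a choice made after the data were seen. For Treg against Teff these 66 were chosen by genes that the comparison also tests, so values of marker genes there are not independent of the choice, nor are those of MS against HC in either cell type.

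**Figure D1:**
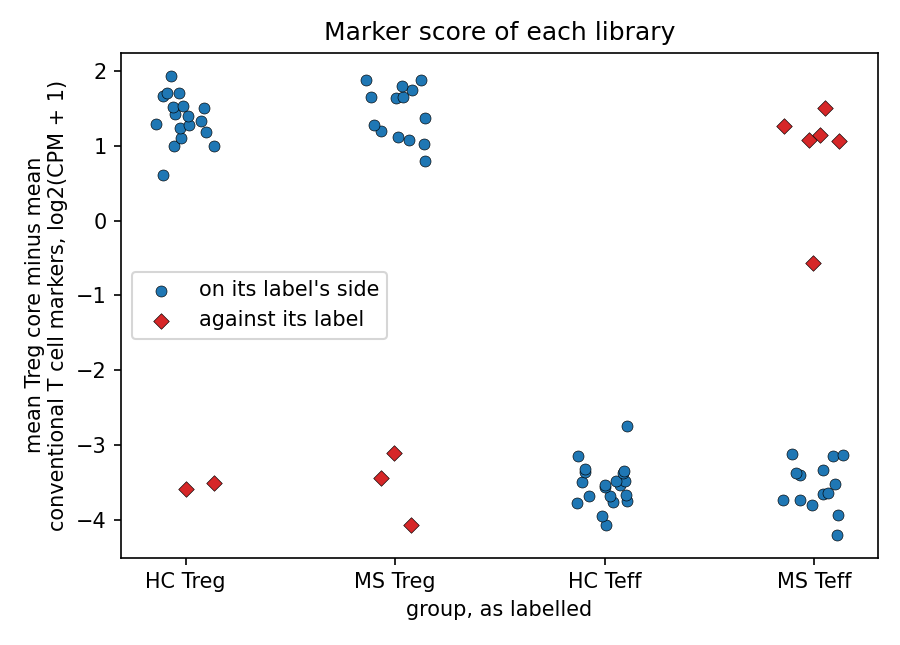
Marker score of each of the 77 libraries (mean log2(CPM + 1) of Treg core genes minus that of conventional T cell genes) by labelled group, with sideways scatter for legibility only. Blue points are the 66 libraries on their label's side and red diamonds the 11 against it, 9 of 37 in MS and 2 of 40 in HC.

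The comparison of memory Treg with memory Teff in healthy controls asks which transcripts set the sorted cell types apart. FOXP3, the transcription factor of the Treg lineage, averaged 85.7 ± 38.9 CPM (SD, n = 20) in Treg and 1.08 ± 0.780 CPM (n = 20) in Teff, a log2 fold change of 6.32 (SE 0.69, adjusted p = 3.33e-10). IL2RA, which encodes the CD25 used for sorting, was higher by 3.37, IKZF2 (Helios) by 5.58, the inhibitory receptors CTLA4 and TIGIT by 3.06 and 2.22, and RTKN2, LAYN and TSHR by 4.29, 9.26 and 6.80. IL7R, which encodes the CD127 used for sorting, was lower by -2.09, and so were the chromatin organiser SATB1 (-1.71), the receptor TGFBR2 (-1.37), STOM (-2.76) and PDCD4 (-1.16). All of these passed the threshold. CD4 itself, carried by both cell types, was slightly lower in Treg (-0.38, adjusted p = 0.0213), a call lost in 2 of 17 alternatives (highest adjusted p = 0.158).

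Of the Treg core list, 26 of 28 genes rose in HC Treg and none fell (median log2 fold change 3.10, 26 adjusted over the list alone; list adjusted p = 1.61e-21, and adjusted p = 0.0768 with an estimated correlation). All 21 proliferation genes were higher, 21 adjusted over the list alone, among them MKI67 (5.18), BIRC5 (5.41) and STMN1 (2.22), with an adjusted p = 0.108 for the list with an estimated correlation. All 11 HLA class II genes were higher as well, 11 adjusted over the list alone, with HLA-DRA at 3.80, HLA-DMA at 2.80 and CD74, the invariant chain, at 1.19; the list had an adjusted p = 0.0804 with an estimated correlation. Of 16 coinhibitory genes 9 were higher and 1 lower (the same numbers adjusted over the list alone), with ENTPD1, an ectonucleotidase, at 3.41 and the cytokine IL10 at 4.93 (adjusted p = 0.108 with an estimated correlation). Ribosomal protein genes were lower in 27 of 44 cases (32 adjusted over the list alone), led by RPL3 at -0.84 (adjusted p = 0.298 with an estimated correlation). Conventional T cell genes were lower in 11 of 15 cases (12 adjusted over the list alone), including THEMIS at -2.73, and the list had an adjusted p = 0.0656 with an estimated correlation. Naive and central memory genes were lower in 9 of 12 cases (10 lower and 1 higher adjusted over the list alone), including TCF7 at -1.83 and the lymph node homing receptor CCR7 at -1.06, with an adjusted p = 0.0768 with an estimated correlation. Cytotoxic genes were lower in 8 of 14 cases and higher in 1 (10 and 1 adjusted over the list alone), with EOMES at -4.65 and GZMK at -2.22, and adjusted p = 0.298 with an estimated correlation.

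Altogether 3325 of 14324 tested genes passed the threshold in HC, 1776 higher and 1549 lower in Treg. The larger direction turned with limma-voom (1447 higher and 1802 lower), with the donor as a random effect (1853 and 2212) and with the replicate block (1914 and 2129). In the 66 libraries on their label's side 4038 of 14121 passed, 2065 higher and 1973 lower. FOXP3 then ranged from 49.4 to 166 CPM over 18 HC Treg and from 0.0615 to 2.84 CPM over 20 HC Teff libraries. In those 66 libraries 8 lists passed with an estimated correlation: Treg core, conventional T cell, proliferation, HLA class II, coinhibitory, naive and central memory, FOXO1 targets and glucocorticoid response.

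**Figure D2:**
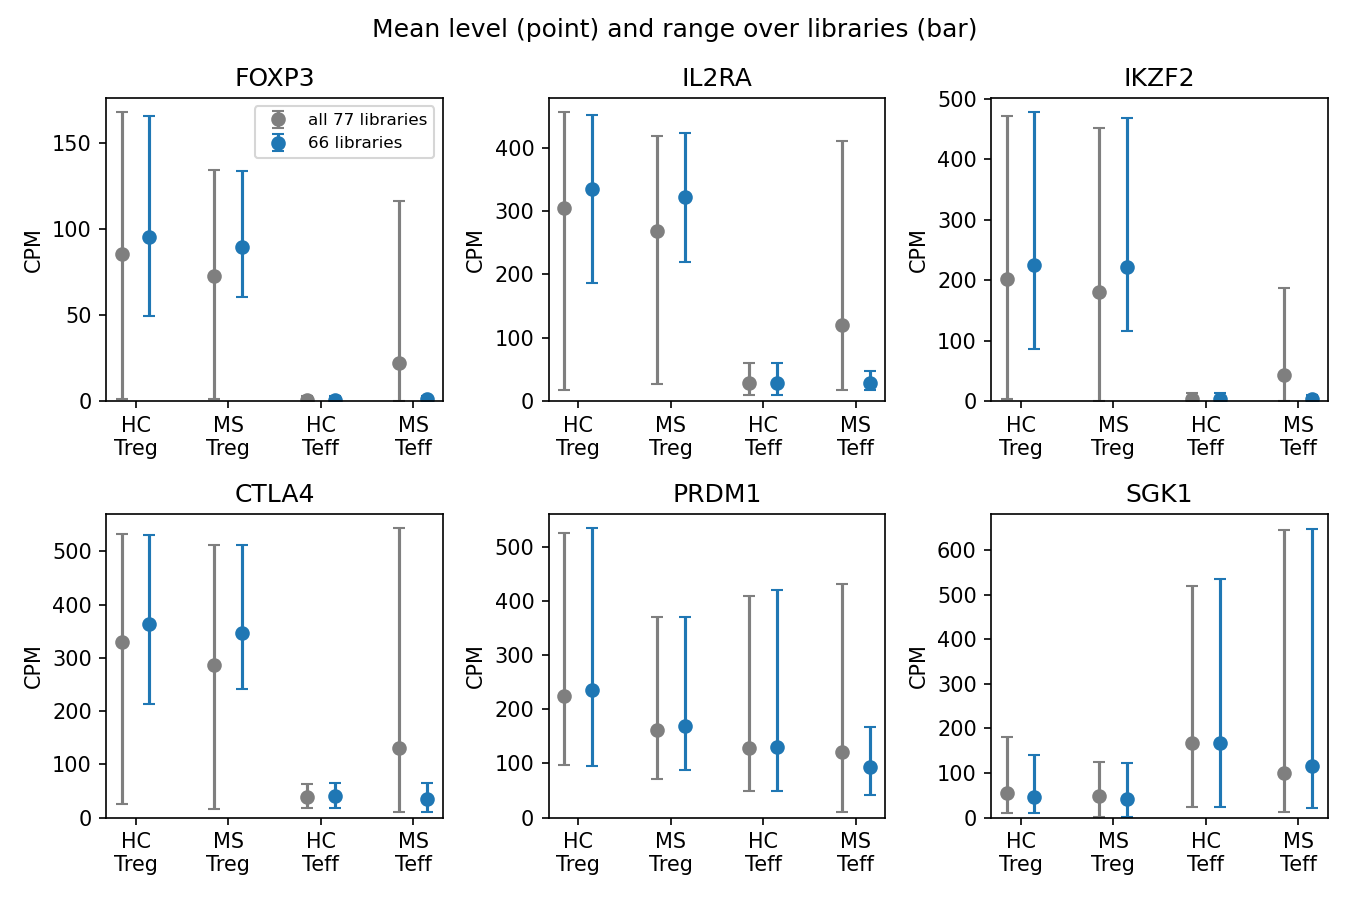
Level in CPM of 6 genes in the 4 groups, with the mean as a point and the lowest to highest library as a bar, for all 77 libraries (grey) and the 66 on their label's side (blue). FOXP3 averaged 22.4 CPM in the 20 MS Teff libraries and 1.54 CPM in the 14 of them on their label's side.

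The same comparison in MS asks whether Treg and Teff differ there as in healthy controls. As labelled, RTKN2 was higher in MS Treg (1.81), as were IKZF2 (2.04), TIGIT (1.24), the interferon-induced GTPase GBP5 (1.13) and CPNE2 (1.73), and SATB1 (-1.31), IL7R (-1.23), UBE2E3 (-1.14), TGIF1 (-1.03) and LGALS3BP (-1.51) were lower. FOXP3 (1.71, adjusted p = 0.0774), IL2RA (1.16, adjusted p = 0.0689) and CTLA4 (1.14, adjusted p = 0.0750) did not pass. These calls depended on the method: FOXP3, IL2RA and CTLA4 passed in 4, 8 and 8 of 17 alternatives, and IL7R, IKZF2 and TIGIT lost theirs in 6, 4 and 3. FOXP3 averaged 73.0 ± 39.2 CPM (SD, n = 17) in MS Treg and 22.4 ± 35.0 CPM (n = 20) in MS Teff. Of the Treg core list 10 of 28 genes were higher (23 adjusted over the list alone; median 1.20), and of the conventional T cell list 5 of 15 were lower (11 adjusted over the list alone); both lists had an adjusted p = 0.0689 with an estimated correlation. HLA class II genes were higher in 3 of 11 cases (9 adjusted over the list alone), with the same adjusted p = 0.0689 with an estimated correlation. As labelled 307 genes passed, 110 higher and 197 lower in MS Treg.

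With the 66 libraries, FOXP3 was higher in MS Treg by 5.82 (SE 0.35, adjusted p = 2.09e-22, 14 Treg against 14 Teff libraries), IL2RA by 3.46, IKZF2 by 5.96, CTLA4 by 3.28, CEACAM4 by 9.79 and TNFRSF9, a costimulatory receptor of activated T cells, by 8.60. IGFBP3 (-8.51), the chemokine CCL5 (-5.18), ADAM23 (-8.48) and SCML4 (-3.13) were lower. Then 3023 genes passed, 1512 higher and 1511 lower. Of these, 1305 higher and 1261 lower genes also passed in that direction in HC, where 221 and 211 would be shared by independent lists, and none passed in opposite directions. Treg core genes were higher in 27 of 28 cases, HLA class II in 11 of 11 and proliferation in 18 of 21 (27, 11 and 19 adjusted over the list alone), and the same 8 lists as in HC passed with an estimated correlation. Across genes, which are not independent replicates, the Treg to Teff fold changes of HC and MS correlated with r = 0.722 as labelled and r = 0.890 in the 66 libraries. Those libraries were kept by the same marker score in HC and MS. How much of the shared calls and of this correlation follows from that choice was not tested.

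Memory Treg of MS and HC were compared to find transcripts that differ with the disease. The transcription factor IRF1 (-0.97), RNF166 (-0.93), RBM38 (-1.78), CORO7 (-1.03), the chromatin gene ASXL1 (-0.94) and the metal-responsive factor MTF1 (-0.83) were lower in MS Treg, and GIMAP7 (0.91), the glutathione peroxidase GPX4 (0.58), TIMM17B (0.50) of the mitochondrial import machinery and SSBP1 (0.50) were higher. Also higher were MTCO1P12 (3.29) and MTND1P23 (5.05), nuclear copies of mitochondrial genes whose reads the counting could have divided with the originals, so their values are uncertain. Immediate early genes, which respond within minutes to stimulation, fell in 3 of 19 cases (6 adjusted over the list alone): JUND (-1.24), FOSL2 (-1.38) and JUNB (-0.80); the list had adjusted p = 8.41e-06, and adjusted p = 0.494 with an estimated correlation. The NF-kB subunit gene RELB was lower by -2.14 and NFKBIZ by -0.83, the members of the 16 NF-kB response genes past the threshold (6 lower adjusted over the list alone; list adjusted p = 0.494 with an estimated correlation). Oxidative phosphorylation genes had positive fold changes in 23 of 27 cases (median 0.22) with none past the threshold over all genes and 5 adjusted over the list alone, and the list rose by camera (adjusted p = 1.21e-05, and adjusted p = 0.494 with an estimated correlation). FOXP3 (-0.23), IL2RA (-0.18) and CTLA4 (-0.20) did not pass in MS against HC Treg.

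As labelled 600 genes passed in Treg, 222 higher and 378 lower in MS. In the 66 libraries 197 passed, 63 higher and 134 lower, and 165 of them were among the 600. Without the 4 Treg libraries rich in MALAT1 72 passed, and without the 2 libraries far from their group 434. In the full set of 66 libraries IRF1 (-1.01), RNF166 (-0.87), GPX4 (0.57), JUNB (-0.95), JUND (-1.29) and the phosphatase gene DUSP2 (-1.25) passed. SOCS3 (-1.97), a feedback inhibitor of cytokine signalling, passed in that set too. With surrogate variables as covariates 18 genes passed as labelled and 2 in the 66 libraries. With the replicate number as a block the larger direction turned, with 322 higher and 282 lower as labelled and 226 higher and 193 lower in the 66 libraries. Numbers do not pair HC with MS, so that block joins different people.

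In memory Teff as labelled, genes of the Treg programme were higher in MS than in HC: FOXP3 by 4.39 (SE 0.65, adjusted p = 8.78e-06), IL2RA by 2.03, CTLA4 by 1.72, IKZF2 by 3.38, TSHR by 5.29 and LAYN by 7.25. Treg core genes were higher in 18 of 28 cases and lower in 1 (19 and 1 adjusted over the list alone; adjusted p = 0.636 with an estimated correlation) and proliferation genes in 18 of 21 (20 adjusted over the list alone; adjusted p = 0.578 with an estimated correlation). Of 20 MS Teff libraries 6 carried Treg markers against their label. In the other 14, FOXP3 averaged 1.54 ± 1.12 CPM, against 1.08 ± 0.774 CPM in 20 HC Teff libraries, and did not pass (0.57, adjusted p = 0.339); IL2RA (-0.01), CTLA4 (-0.16) and IKZF2 (-0.25) did not pass either. These genes are part of the score by which the 6 libraries were left out, so the loss of their difference follows from that choice. As labelled 1635 genes passed, 975 higher and 660 lower in MS. With limma-voom the larger direction turned (696 higher and 811 lower), and with surrogate variables 8 genes passed as labelled and 3 in the 66 libraries.

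In the 66 libraries on their label's side 98 genes passed in Teff, 38 higher and 60 lower in MS, 90 of them among the 1635. The count moved both ways with the setting, to 375 with DESeq2, 586 with the replicate block (which joins different people) and 384 without the 4 Treg libraries rich in MALAT1. The costimulatory receptor ICOS (-1.08, SE 0.21, adjusted p = 0.00576), RNF166 (-0.81), ARRDC2 (-1.21), ATXN7 (-0.86) and FAM46C (-1.03) were lower in MS Teff, and FMC1 (0.83), TIMM17B (0.49), POLR3K (0.94) and SNAPIN (0.87) were higher. The platelet genes PF4 (-4.97), PPBP (-5.06), SDPR (-4.83) and GNG11 (-4.69) were lower, 4 of 6 measured platelet markers (5 adjusted over the list alone; list adjusted p = 0.00039, and adjusted p = 0.518 with an estimated correlation). These 4 calls rested on the HC Teff library with the most platelet reads, 1135 CPM against a group median of 22.2 CPM. Without it PF4 was at -1.91 (adjusted p = 0.258), none of the 6 platelet genes passed, and 31 genes passed in all, 18 higher and 13 lower in MS. In the 66 libraries NF-kB response genes had negative fold changes in 13 of 16 cases (none past the threshold over all genes, 3 adjusted over the list alone), and the list fell (adjusted p = 0.000935, and adjusted p = 0.518 with an estimated correlation).

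**Figure D3:**
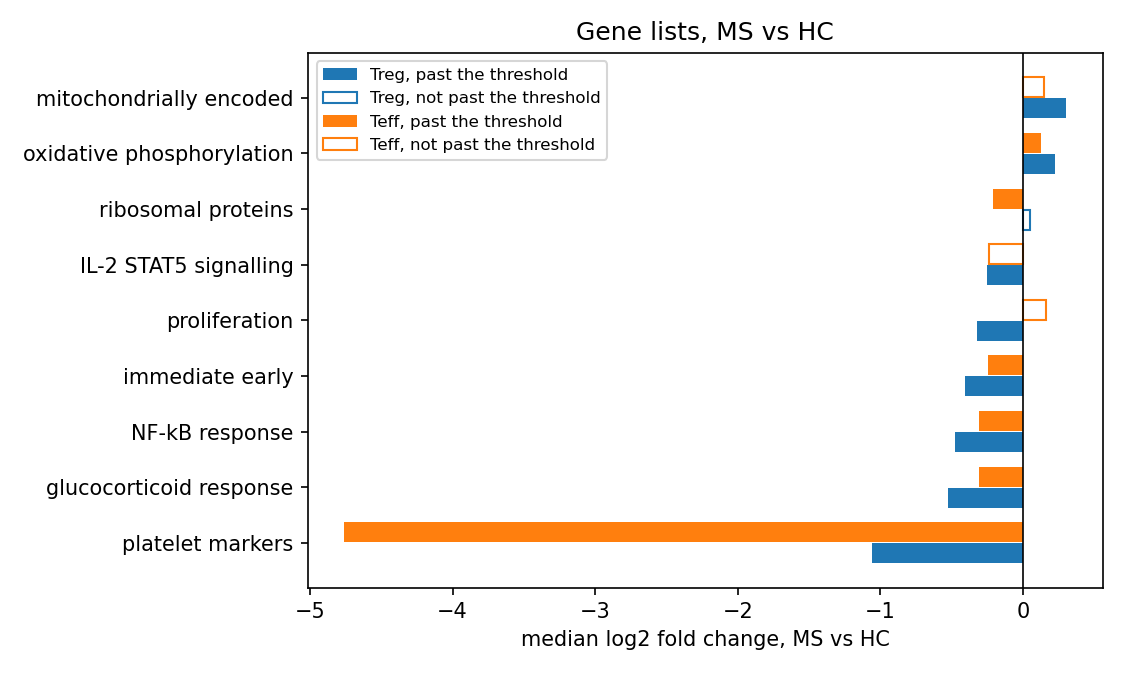
Median log2 fold change of MS against HC in Treg (blue) and Teff (orange) for each gene list past the threshold by camera with preset correlation in either cell type, in the 66 libraries on their label's side. Filled bars passed and open bars did not, and no list passed with an estimated correlation.

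The interaction asks whether MS against HC differs between Treg and Teff. As labelled 57 genes passed, all with a lower MS against HC fold change in Treg than in Teff, among them FOXP3 (-4.62, SE 0.85, adjusted p = 0.0026), LAYN (-7.59), TNFRSF9 (-5.49) and BIRC5 (-5.50). No gene passed as labelled with limma-voom, with the donor as a random effect or with the replicate block, and FOXP3 lost its call in 4 of 16 alternatives. Without the libraries against their label edgeR called 0 genes, with 249 at an unadjusted p under 0.05, while DESeq2 called 1 and limma-voom 0. Those 249 are a smaller share of the 14121 tested genes than the 0.05 that no difference would give on average. The edgeR fit was thus cautious here, and it did not use that libraries of the same number deviated together. Fits with the donor as a random effect or the replicate block, which use it, also called 0 in those libraries. In edgeR, CCR3 (6.38, adjusted p = 0.0986) and WNT7A (3.16, adjusted p = 0.423) had the smallest p among higher genes. Among lower genes these were TSHR (-2.40, adjusted p = 0.452) and TUBB (-0.68, adjusted p = 0.801). Ribosomal protein genes were the list that passed in those libraries, with all 44 fold changes positive (median 0.24) and 0 genes past the threshold over all genes or adjusted over the list alone; the list had adjusted p = 1.25e-10, and adjusted p = 0.836 with an estimated correlation. The fold changes of MS against HC in Treg correlated across genes with those in Teff at r = 0.380 (rho = 0.546) as labelled and r = 0.507 (rho = 0.600) in the 66 libraries. When donors were divided at random 100 times, the mean r was 0.109 as labelled and 0.201 in the 66 libraries and the highest 0.375 and 0.451. In the 66 libraries 10 higher genes, TIMM17B and MTND1P23 among them, and 20 lower genes, RNF166 and FAM46C among them, passed in both cell types, which share donors.

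PRDM1, which encodes the transcription factor Blimp-1, and SGK1, a kinase induced by salt and glucocorticoids, had been chosen beforehand. PRDM1 averaged 224 ± 119 CPM (SD, n = 20) in HC Treg and 129 ± 84.3 CPM (n = 20) in HC Teff, a log2 fold change of 0.79 (SE 0.25, adjusted p = 0.0154), and SGK1 was lower in HC Treg by -1.59 (SE 0.40, adjusted p = 0.00153). With surrogate variables neither passed as labelled (SGK1 -0.59, adjusted p = 0.268, and PRDM1 0.47, adjusted p = 0.204). In the 66 libraries both passed in HC (PRDM1 0.86, adjusted p = 0.00159, and SGK1 -1.85, adjusted p = 6.07e-05) and kept their calls in all 17 alternatives. For Treg against Teff in MS neither passed as labelled (PRDM1 0.41, adjusted p = 0.412, and SGK1 -1.03, adjusted p = 0.151). Both passed there in the 66 libraries (PRDM1 0.86, adjusted p = 0.0092, and SGK1 -1.46, adjusted p = 0.0080). In MS against HC as labelled neither passed in Treg (PRDM1 -0.46, adjusted p = 0.301, and SGK1 -0.16, adjusted p = 0.857). The same held in Teff (PRDM1 -0.08, adjusted p = 0.864, and SGK1 -0.72, adjusted p = 0.219). In the 66 libraries neither passed in Treg (PRDM1 -0.49, adjusted p = 0.252, and SGK1 -0.15, adjusted p = 0.867). Nor did they pass there in Teff (PRDM1 -0.49, adjusted p = 0.262, and SGK1 -0.55, adjusted p = 0.476). As labelled, SGK1 was lower in MS Teff past the threshold in 3 of 17 alternatives, limma-voom with and without the donor and the replicate block (lowest -1.22, adjusted p = 0.0249). Counts per gene cannot tell the transcript isoforms of PRDM1 apart. Across Treg libraries on their label's side, PRDM1 and SGK1 correlated with r = 0.380 (permutation p = 0.121, adjusted p = 0.180) and rho = 0.218 (permutation p = 0.385) in 18 HC libraries. In 14 MS libraries r was -0.379 (permutation p = 0.180, adjusted p = 0.180) and rho -0.582 (permutation p = 0.0320), all two-sided, with 2 relations in the family and 100000 resamples. Without the 2 libraries farthest from the median of PRDM1, r was 0.0414 and rho -0.0706 in HC (permutation p = 0.877 and 0.796), and r was -0.119 and rho -0.503 in MS (permutation p = 0.718 and 0.0989). The p-values of rho were not adjusted over the 2 relations. Correlations over all Treg libraries as labelled, which had been planned, were not computed. The difference between both correlations was not tested.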

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

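The tests of an exchange in numbers with 1 library against its label, of a mixture and of the frequency in MS, over libraries and over numbers, were chosen only after the result was seen. The interaction test, which compares MS against HC between Treg and Teff, set apart 57 genes as labelled, a difference between groups. The log2 values were -7.59 for LAYN, -5.22 for TSHR, -4.62 for FOXP3, -6.23 for CSF2RB, -4.80 for TRIB1, -6.20 for PMCH, -5.50 for BIRC5, -5.49 for TNFRSF9, -2.21 for IL2RA and -3.55 for IKZF2. The call was lost in 4 of 16 alternatives for FOXP3, in 8 for IL2RA and in 6 for IKZF2, whose sign also reversed in 1 more. The same test by camera set apart 9 lists, with medians of 0.31 for ribosomal proteins, -2.83 for proliferation, -1.64 for Treg core, 0.77 for conventional T cell, -1.51 for HLA class II, 0.63 for Th1, 0.23 for mitochondrially encoded, 1.07 for gamma delta T cell markers and -0.49 for coinhibitory genes. With an estimated correlation none of the 9 passed (adjusted p between 0.325 and 0.612), and without the libraries against their label the interaction gave 0 genes and 1 list.

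The interaction gave 0 genes without the 11 libraries whose Treg and conventional T cell markers go against their label, 9 of 37 in MS and 2 of 40 in HC. A mixture of both cell types in a library is argued against for 10 of the 11, whose marker score lay within the range of the other cell type, while 1 lay between. An exchange of Treg and Teff within a number is argued against in 3 numbers whose partner library carried the markers of its own label. It was not decided for the 3 numbers with both libraries against their label. Once exchanged, 2 of these correlated at 0.1 or less (lowest -0.181), which the bound written beforehand would read as evidence against. The other 1 had r = 0.177, and 0 of the 6 libraries matched their own number best. MS pairs in place had r of 0.12 to 0.478, but on an unlike measure. The exchanged pairs were correlated without XIST, its antisense gene and Y-linked genes, and against group means that did not include them. An exchange with another number was not tested and stays open. A change of cell identity that goes with MS could not be decided: over libraries Fisher's exact test gave a two-sided p = 0.0218, but over numbers, 6 of 21 in MS and 2 of 21 in HC, it gave p = 0.238, and an unlabelled batch with more MS libraries would give the same.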

How the results depend on the processing

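Every setting without the libraries against their label, the offsets for GC content and length, surrogate variables for the correlations of fold changes, the loss of Treg libraries rich in MALAT1 and that of the library richest in platelet reads were chosen only after the result was seen, and the cause was not tested unless a smaller number of genes, libraries or calls follows from the setting itself. The count for Treg against Teff in HC stayed between 2633 and 4065 in 16 of 18 alternatives, and was 2007 with surrogate variables and 1996 at a threshold of 0.01. For Treg against Teff in MS (307 as labelled) the count was 610 with DESeq2, 1001 with limma-voom, 1711 with the donor as a random effect, 1253 with the replicate block, 96 with only the groups compared, 192 without libraries far from their group, 8 at 0.01, 0 with surrogate variables in edgeR, and 3023 without the libraries against their label. For MS against HC in Treg (600) it was 1165 with DESeq2, 163 with only the groups compared, 901 with only donors with both cell types, 904 without libraries far from their group, 18 with surrogate variables, 24 at 0.01 and 197 without the libraries against their label. For MS against HC in Teff (1635) it was 8 with surrogate variables, 514 at 0.01 and 98 without the libraries against their label. For the interaction (57) it was 0 with limma-voom, with the donor as a random effect, with the replicate block and without the libraries against their label, 27 at a mean CPM of at least 5, 14 with only donors with both cell types, 29 with detected genes as a covariate, 16 with surrogate variables and 17 at 0.01.

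Without the libraries against their label, the count in HC (4038) stayed between 2808 and 5289, the latter with the replicate block. In MS (3023) it was 4725 with the donor as a random effect and 1986 at 0.01. MS against HC in Treg (197) gave 679 with DESeq2, 355 with the donor as a random effect, 399 at a mean CPM of at least 5, 45 with only the groups compared, 419 with the replicate block, 2 with surrogate variables, 124 with the sex-linked covariate, 434 without libraries far from their group, 5 at 0.01 and 72 without the Treg libraries rich in MALAT1. MS against HC in Teff (98) gave 375 with DESeq2, 261 with the donor as a random effect, 236 with only the groups compared, 61 with only donors with both cell types, 586 with the replicate block, 3 with surrogate variables, 206 without libraries far from their group, 10 at 0.01, 384 without the Treg libraries rich in MALAT1 and 31 without the library richest in platelet reads. The interaction (0) gave 1 with DESeq2, 5 with no filter and 1 with surrogate variables.

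With a correlation estimated per list, the number of lists past the threshold was 0 in each comparison as labelled; fry gave 8 for Treg against Teff in MS and 0 for the interaction. Without the libraries against their label camera gave 6 lists in MS against HC in Teff and 1 in the interaction; with an estimated correlation it gave 8 in HC and 8 in MS for Treg against Teff and 0 in the other comparisons, and fry 1, 2 and 0 in MS against HC in Treg, in Teff and in the interaction. The correlation of MS against HC fold changes between Treg and Teff was 0.570 at a mean CPM of at least 5, 0.135 with surrogate variables, and 0.220 and 0.221 with different donors as labelled; in the 66 libraries it was 0.309 with surrogate variables and 0.246 and 0.239 with different donors.

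Of the focal genes, TIGIT in MS against HC in Teff reversed with surrogate variables (-0.020), and without the libraries against their label so did IL2RA (-0.0096), CTLA4 (-0.16) and IKZF2 (-0.25) in that comparison and IKZF2 in the interaction (0.22), none past the threshold after the change. Other focal tests as labelled kept their side of the threshold in 668 cases (the sign could differ where neither value passed), lost the call in 56 and gained it in 27; without the libraries against their label the numbers were 753, 1 and 2. Libraries of the same number correlated best with their own number for 13 of 19 HC pairs and 1 of 16 MS pairs as labelled, and for 13 of 17 and 11 of 12 without the libraries against their label; numbers do not pair HC with MS, so the replicate block there joins different people. Depth was not varied. At the depth of these libraries, simulated changes of 1 on the log2 scale were found in 43% to 50% of cases and changes of 0.5 in 6% to 18%. Small changes were thus mostly missed in a simulation with few changed genes, independent libraries and no hidden structure. These shares, and the few unchanged genes called, need not carry over to the real comparisons.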

Other observations

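All tests of shared fold changes and of platelet RNA had a bound written before their result was seen, while the libraries left out, the offsets for GC content and length and the loss of the library richest in platelet reads were chosen only after the data were seen. In the 66 libraries on their label's side, genes of the MS risk list did not move together: in Teff 1 of 24 was higher (CD58, the ligand of CD2, 0.94, adjusted p = 0.0461) and 1 lower (STAT3, a transcription factor of cytokine signalling, -0.72, adjusted p = 0.0266), both named after the values were seen, with 1 and 6 adjusted over the list alone and a list adjusted p = 0.447. In Treg STAT3 was lower (-0.63, adjusted p = 0.0410) and the list had an adjusted p = 0.533. The type I interferon response list did not pass either (adjusted p = 0.818 in Treg and 0.496 in Teff, medians -0.01 and 0.11). The mitochondrially encoded list had 13 of 13 positive fold changes in MS Treg (median 0.31), with 0 genes past the threshold over all genes and 3 adjusted over the list alone; by camera it passed (adjusted p = 0.00072, and adjusted p = 0.566 with an estimated correlation). As labelled these genes took 5.19% of counts in MS Treg (SD 0.789, n = 17) and 4.66% in HC Treg (SD 0.989, n = 20).

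Markers of other blood cells went both ways in HC Treg against HC Teff as labelled. Platelet markers were lower in 6 of 6 cases (6 adjusted over the list alone), with TUBB1 at -3.31 and PF4 at -2.73, but the list did not pass by camera (adjusted p = 0.138). Without the HC Teff library with the most platelet reads 1 of the 5 genes left after the filter passed. The median went from -2.64 over 6 genes to 0.18 over 5. In the 66 libraries, with 6 genes either way, it went from -3.08 to -0.44. B cell markers were higher in 3 of 6 cases and lower in 1 (3 and 2 adjusted over the list alone), with CD79A, of the B cell receptor complex, at 1.82 and MS4A1, which encodes CD20, at -2.81 (list adjusted p = 0.192). NK cell markers were higher in 2 of 7 cases and lower in 2 (2 and 2 adjusted over the list alone), with FCER1G, a signalling chain of Fc receptors, at 3.51 and the granule protein gene GNLY at -3.07 (list adjusted p = 0.939). Gamma delta T cell markers were lower in 3 of 4 cases (3 adjusted over the list alone; median -2.65), with adjusted p = 0.108 with an estimated correlation. Monocyte markers (median 1.64, adjusted p = 0.372) and NK cell markers (median 0.50, adjusted p = 0.215) did not pass in MS against HC Treg in the 66 libraries. Platelet markers did pass as a list in that comparison by camera with preset correlation, though not with an estimated one. None of their genes passed, with TUBB1 at -2.63 (adjusted p = 0.170), CLU at -0.83, PPBP at -1.26 and GNG11 at -1.14.

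The fold changes of MS against HC were shared by Treg and Teff (r = 0.507 in the 66 libraries). Donors common to both comparisons are argued against as the whole cause, since r was 0.246 and 0.239 with different donors on each side, above the 95th percentile of 100 random divisions (0.183 and 0.126), of which 4 and 0 reached the real r. Gene length and GC content are argued against as well, since r was 0.496 with offsets for both. Hidden structure of the libraries remains a candidate explanation: with surrogate variables the median absolute log2 fold change of the 197 genes called in Treg went from 0.80 (middle range 0.62 to 1.05) to 0.35 (0.24 to 0.57) and that of the 98 called in Teff from 0.90 to 0.43, with 1 and 2 still past the threshold, while 195 and all 98 kept their sign. A difference between people with MS and controls that the surrogate variables absorbed stays open too, as untested.

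Platelet genes were lower in MS Teff. Platelet RNA carried along with the cells, which sorting on CD4 does not exclude where platelets adhere, may account for it, but the test did not decide: 13 platelet transcripts outside the list had a median log2 fold change of -0.16 (lowest -3.04), which the bound written beforehand would read as evidence against, yet only 3 of the 13 had a mean under 1 CPM in MS Teff, so the level in T cells could hide a small share. A few rich HC Teff libraries are the other candidate: 7 of 20 lay above the highest MS Teff library in summed platelet CPM, a number between the bounds set beforehand. Without the richest of them the 4 platelet calls became 0. No biological explanation was tested.

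Other divisions of the same libraries bear on how readily each count of genes arises by chance. As labelled, 1 of 60 divisions, the real one, gave as many genes in Treg against Teff in HC (3325, highest other 5) and in MS (307, highest other 4). The same held for MS against HC in Teff (1635, highest other 94) and for the interaction (57, highest other 49). With 60 divisions the share cannot fall below 1 of 60, so chance is not excluded, and in the interaction another division came near. In Teff and in the interaction the divisions do not tell how the libraries against their label came to lie in MS, since without them the counts were 98 and 0. In MS against HC in Treg 2 of 60, the real one included, gave as many as 600, with the highest other at 609; the share is under 0.05, but another division matched the groups. Without the libraries against their label, 1 of 60 gave as many for Treg against Teff in HC (4038, highest other 1737) and MS (3023, highest other 938). Other divisions there exchanged cell types within pairs. These libraries had been kept because their markers fit the Treg and Teff labels, so that outcome follows from the choice and does not bear on chance. In MS against HC in Treg 1 of 60 gave as many too (197, highest other 9). In MS against HC in Teff 2 of 60, the real one included, gave as many as 98, and the highest other gave 531, several times as many. Why that division gave more genes was not tested.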
